A study of Rattus norvegicus with 38 samples.

How the data were processed

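The measurements were 3' end RNA sequencing of material cut by laser microdissection from the frontal brain of rats. RNA was isolated with the PicoPure kit and libraries were made with Lexogen's QuantSeq 3' mRNA-Seq forward kit, per the labels' protocols. Such libraries place their reads near the 3' end of a transcript, so a count does not grow with transcript length, and a gene whose 3' end is placed wrongly in an annotation loses counts. The 38 libraries came from 19 numbered animals, each with 1 library from cortical blood vessels (vessel libraries below) and 1 from clusters of cortical neurons (neuron libraries). How the pieces of tissue were picked for cutting is not given in the sources used here.

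The authors deposited 1 table of whole-number counts per Ensembl gene ID (ID below), with 32883 IDs and 38 columns, each column named for its sample's title. The submitters' processing notes name FastQC 0.11.5, STAR 2.5.3a, HTSeq 0.6.1 and DESeq2 1.18.1. The genome build, the annotation and the strand setting of the counting are not given in the sources used here. The values were whole and their totals differed between libraries, so they were treated as counts without normalization. No row without a gene ID was present, and 0 columns lacked a sample. Genes that overlap or that have near-identical copies cannot be separated further from such counts.

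The table gives IDs without gene names. The reference table used here, of the rat assembly GRCr8, has no Ensembl IDs, and 0 of the 32883 IDs matched it. The 39 gene lists and the rule for naming genes, both set before the data were examined, need gene names and could not be applied. In their place, the text prints for each comparison at most the 2 higher and 2 lower IDs with the smallest p, a rule set after the table turned out to hold no names and before the values were looked at. IDs named for another reason are said to be so. Groups of IDs were instead formed from the data. An ID was called vessel-enriched or neuron-enriched where the comparison of the materials passed its threshold with a log2 fold of at least 1 in either direction. These groups describe the captured material and are not cell type markers.

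Groups followed the labels: Wistar or SHRSP, early or late stage. Within each material, edgeR 4.0.16 in R 4.3.3 was fitted to all 19 libraries with the 4 groups as terms, after the filter on low counts that edgeR bases on group sizes. Scaling was by TMM, dispersions were estimated with the design, and the quasi-likelihood F test was run with robust shrinkage. It tested 11011 IDs in vessels and 10833 in neurons. The 6 contrasts per material were the strain difference early, late and as the mean of both stages, its change with stage, and the stage difference in each strain. Vessels were compared with neurons, and the strain difference between the materials, over all 38 libraries and 12117 IDs with the animal as a block. Tests were two-sided, except Fisher's exact tests of overlap and a binomial test named as one-sided, and calls are IDs with a Benjamini-Hochberg adjusted p under 0.05 over the IDs tested. A standard error (SE) of a log2 fold is the fold divided by the square root of its F statistic. Levels are given as CPM, counts scaled by the TMM-adjusted totals of the fit they belong to, so a level given for the comparison of materials differs slightly from that of the same libraries within a material. Replicates are separately numbered animals, so the p-values measure the spread between animals together with that of cutting and library making. That spread is shrunk towards values shared over IDs. The fit across materials gives both materials the same spread per ID, although their coefficients of variation differed (1.59 in vessels and 0.354 in neurons). Its very small p-values are therefore no exact measure of the spread between animals.

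The animal number in the titles ties a vessel library to a neuron library, and the block rests on reading that number as the animal. Over IDs with a mean log2 CPM of at least 5, the deviations of the 19 pairs from their group means correlated between -0.231 and 0.407, with a median of 0.0473 and 5 pairs over 0.1, against a median of -0.00727 for libraries of different numbers. Within groups, 72 pairs of libraries were compared by chi-square over IDs with at least 10 counts in the pair, and the smallest value per degree of freedom was 4.88, so no pair within a group differed as little as repeated counts of the same library would. Pairs across groups were not compared.

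Totals lay between 1612966 and 4963429 counts in vessels (median 3097536) and between 1198386 and 4101901 in neurons (median 2922937). For comparing detection at equal depth, the expected number of IDs was computed at 1198386 counts per library. The libraries carry no molecular identifiers that were used here, so limits from counts cover counting error only. A fold against a group with no counts was bounded with 3 counts over that whole group. The typical variation between animals (common biological coefficient of variation) was 1.59 in vessels and 0.354 in neurons.

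The most abundant ID, ENSRNOG00000043866, took very different shares of the counts. Among neuron libraries its share had a gap between 10.7% and 20.4%, and this gap was used, after seeing the data, to part the animals into 8 with a low share and 11 with a high share. These 2 sets of libraries are not groups of the study.

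Scripts were tested on simulated counts drawn from the means and totals of the real libraries, with 100 IDs changed 2-fold and 100 changed 8-fold. The neuron contrasts recovered 9% to 55% of the 2-fold and 81% to 98% of the 8-fold changes. In vessels, 8-fold changes were recovered in 2% to 6%, except for the mean of stages, where 28% were. The comparison of materials recovered 4% and 49%, and the strain difference between materials 0% and 16%.

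Alternatives planned before the data were examined were scaling by DESeq2-type size factors, no filter and another filter on low counts (at least 10 counts in at least 4 libraries of each material fitted), DESeq2 1.42.0, limma voom 3.58.1 with quality weights, only the 2 groups compared, each animal left out in turn, and no animal block. Alternatives added after seeing the data were the library set as a term, either set alone, and the stage comparisons without the early animals 349 and 383. Single values per library were compared by exact two-sided permutation tests. Predictions for the tests of explanations were written down first, except those that the closing section names as chosen later. Those that use the high-share animals could be worded only once the library sets had been seen in the data. Some of the first were reworded after values were seen and then restored to their first wording. A share was taken to pass a written bound only with its whole exact binomial 95% interval, a reading fixed after the values were seen. Other splits of the animals were refitted 100 times per contrast, or 40 times in limma voom for the comparisons across materials. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.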

Results

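Gene expression was measured in blood vessels and in clusters of neurons cut from the frontal cortex of Wistar rats and of SHRSP rats, the stroke-prone strain of the spontaneously hypertensive rat. The early stage was 24 to 25 weeks of age and the late stage 32 to 34 weeks. Each material had 5 early Wistar, 4 late Wistar, 5 early SHRSP and 5 late SHRSP libraries, from the same 19 animals. The series title asks how the signature of hypertension depends on its stage. Totals ranged from 1198386 to 4963429 counts per library. Genes are given by their Ensembl IDs, because the files do not pair them with names.

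Neuron libraries held 9501 to 14305 IDs with at least 1 count, and vessel libraries 4104 to 11974. The most abundant ID, ENSRNOG00000043866, took 4.34% to 35.5% of the counts in neurons and 6.45% to 40.6% in vessels. In neurons its share averaged 9.13% ± 7.10 in early SHRSP and 11.2% ± 7.91 in early Wistar animals (SD, n = 5 each), against 23.1% ± 2.63 (n = 5) and 32.5% ± 5.48 (n = 4) in the late groups. The same animals stood apart in vessels by the IDs detected, where the 8 animals with a low share in neurons had 6258 ± 1284 and the 11 others 10867 ± 737 (SD). By the share of the most abundant ID these sets overlapped in vessels, at 6.45% to 16.3% against 9.69% to 40.6%. All 9 late animals were in the high-share set, together with 1 early animal of each strain, Wistar 349 and SHRSP 383. Stage and library set therefore coincided in 17 of the 19 animals.

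**Figure D1:**
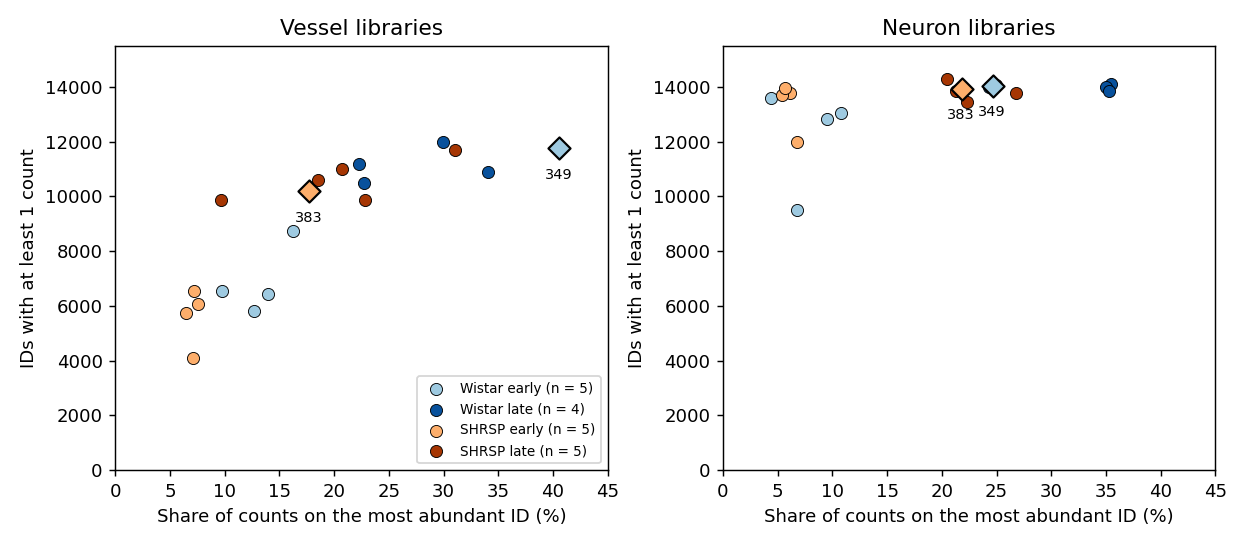
Share of counts on the most abundant ID (percent, x axis) against the number of IDs with at least 1 count (y axis), 1 point per library, for vessels and neurons. The early animals 349 and 383, drawn as diamonds, lie with the late animals, and the low-share vessel libraries held 4104 to 8752 IDs against 9875 to 11974 in the others.

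Vessel and neuron captures differed in the expression of 4157 of 12117 IDs, 416 of them higher in vessels and 3741 higher in neurons. ENSRNOG00000015550 was 72.5-fold higher in vessels (log2 fold 6.18, SE 0.18, adjusted p = 7.88e-199), with 5332 ± 2553 CPM in early SHRSP vessels and 46.6 ± 14.1 CPM in the neurons of the same 5 animals (SD, both on the scale of the 38 libraries together). ENSRNOG00000057880 was 62.0-fold higher in vessels (log2 fold 5.96, SE 0.28). Such small p-values rest on a spread shared by both materials and shrunk over IDs, not on the animals alone. On the neuron side the smallest p belonged to abundant IDs with moderate folds, ENSRNOG00000016156 at log2 fold -1.25 (SE 0.11) and ENSRNOG00000033134 at -1.27 (SE 0.14). With a log2 fold of at least 1 required, 383 IDs were vessel-enriched and 3582 neuron-enriched. Vessel-enriched IDs made up 3.20% to 9.05% of the counts in high-share vessel libraries and 0.649% to 1.09% in high-share neuron libraries.

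The median log2 fold of all IDs tested between the materials was -1.28, and DESeq2-type scaling moved it by 0.21. The 3741 IDs thus lie on a general shift towards neurons. Both IDs named on the neuron side lie near this median. A log2 fold of -1 or lower was found in 57.6% of the IDs tested. An ID called neuron-enriched is therefore not always higher in neurons than a typical ID. Fewer IDs were detected in vessels, and whether this caused the shift was not tested. In the 11 high-share animals alone, 3469 IDs passed, of which 1176 were higher in vessels and 2293 in neurons; 402 of the 416 vessel calls and 1578 of the 3741 neuron calls were among them. In the 8 low-share animals alone 3466 passed, 86 higher in vessels and 3380 in neurons. Without the animal block, 2013 IDs passed, 848 higher and 1165 lower in vessels.

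In neurons, the strains differed in 73 IDs over the mean of both stages, 36 higher and 37 lower in SHRSP. ENSRNOG00000005826 was 15.8-fold higher in SHRSP (log2 fold 3.98, SE 0.39, adjusted p = 1.45e-06) and higher in each of the 10 SHRSP libraries than in any of the 9 Wistar libraries. Its level was 33.0 ± 10.1 CPM in early and 24.9 ± 5.20 in late SHRSP neurons (SD, n = 5 each), against 2.13 ± 1.70 in early (n = 5) and 1.52 ± 1.69 in late Wistar neurons (n = 4). ENSRNOG00000017895 was 29.7-fold lower (log2 fold -4.89, SE 0.44, adjusted p = 7.53e-07), at 0.940 ± 0.805 and 1.40 ± 2.07 CPM in SHRSP and 43.0 ± 19.4 and 32.8 ± 10.4 CPM in Wistar, with no overlap of the strains. ENSRNOG00000038999 was 3.42-fold higher (log2 fold 1.78, SE 0.22) and ENSRNOG00000001199 was 7.30-fold lower (log2 fold -2.87, SE 0.35).

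The 73 IDs had a median absolute log2 fold of 1.31, from 0.45 to 6.05, and 17 of them differed at least 4-fold. In 12 of the 73 the strains' libraries did not overlap, and over all 10833 IDs tested, without choosing by the test, 13 did not overlap, where chance gives 0.235. All 73 had the same sign in the early and in the late animals, and 67 reached an unadjusted p under 0.05 with that sign in the late animals; the IDs were chosen on the mean of both stages, so the shared sign is partly built in. Of the 73, 10 higher and 14 lower IDs were neuron-enriched and 3 higher and 1 lower were vessel-enriched. The count was 30 in the 11 high-share animals alone, and 207 there in limma voom. In these animals 71 of the 73 kept their sign at an unadjusted p under 0.05. Their libraries helped to choose the IDs, so this too is partly built in. Over all animals DESeq2 gave 159 calls and limma voom 180, 112 higher and 68 lower. The edgeR count was 122 without Wistar animal 343, 47, 40 and 46 without the late Wistar animals 350, 353 and 354, and 48 without late SHRSP animal 378.

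**Figure D2:**
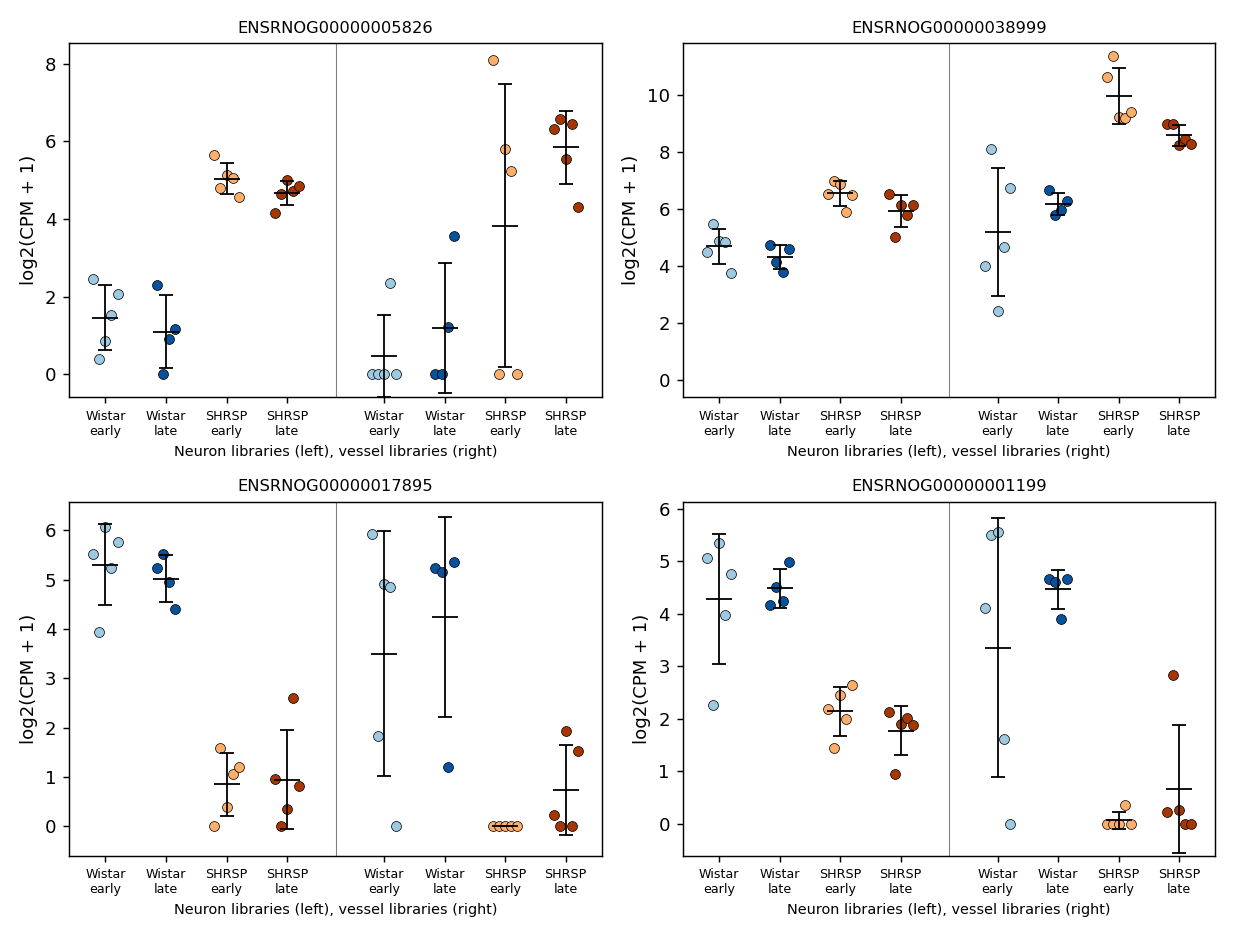
Expression of the 2 higher and 2 lower IDs with the smallest p for the strain difference in neurons, as log2(CPM + 1) per library (points), with the mean and SD of each group (lines), for neuron libraries (left of the grey line) and vessel libraries (right). In neurons ENSRNOG00000005826 and ENSRNOG00000017895 separate the 10 SHRSP from the 9 Wistar libraries.

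Taken by stage, 24 IDs differed between the strains in early neurons, 15 higher and 9 lower in SHRSP, and 4 in late neurons, 1 higher and 3 lower. Early calls included ENSRNOG00000010915, 3.05-fold higher in SHRSP (log2 fold 1.61, SE 0.26, adjusted p = 0.0058), and ENSRNOG00000023086, 3.45-fold lower (log2 fold -1.79, SE 0.31, adjusted p = 0.0112). The late calls included ENSRNOG00000005826 (log2 fold 4.08), ENSRNOG00000017895 (-4.48) and ENSRNOG00000001199 (-3.05). All 4 late calls were also early calls in the same direction, against 0.00138 higher and 0.00249 lower IDs for independent lists (Fisher's exact test, p = 0.00138 and 3.97e-10). No library is shared by the stages, but both contrasts come from the same fit and its estimate of the spread, so the lists are not fully independent. All 24 early calls had the same sign in late animals, 19 of them at an unadjusted p under 0.05. A change of the strain difference with stage was not detected in neurons, where simulated 2-fold changes were found in 9% of cases: 0 passed in edgeR and 254 had an unadjusted p under 0.05, where chance gives 541.6, and DESeq2 and limma voom also gave 0 calls. Early calls numbered 5 with the 2 groups alone and 1 in the low-share animals alone, and late calls 17 and, in the high-share animals, 19. DESeq2 gave 73 early and 16 late calls, and limma voom 60 early and 35 late, the late ones 20 higher and 15 lower. Without single animals, early calls numbered 14 (340), 15 (368 or 374) and 8 (377, 380 or 386), and late calls 2 (354). ENSRNOG00000010915 did not pass early with the 2 groups alone (adjusted p = 0.0636) or in the low-share animals (0.140), over its alternatives 9.11e-06 to 0.140. Nor did ENSRNOG00000005826 pass early in the low-share animals (0.0625, over its alternatives 5.19e-15 to 0.0625). ENSRNOG00000023086 did not pass early without animal 386 (adjusted p = 0.0551) or in the low-share animals (0.0625, over its alternatives 1.54e-05 to 0.0625), nor ENSRNOG00000001199 late without animal 354 (adjusted p = 0.0705, over its alternatives 7.90e-06 to 0.0705).

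**Figure D3:**
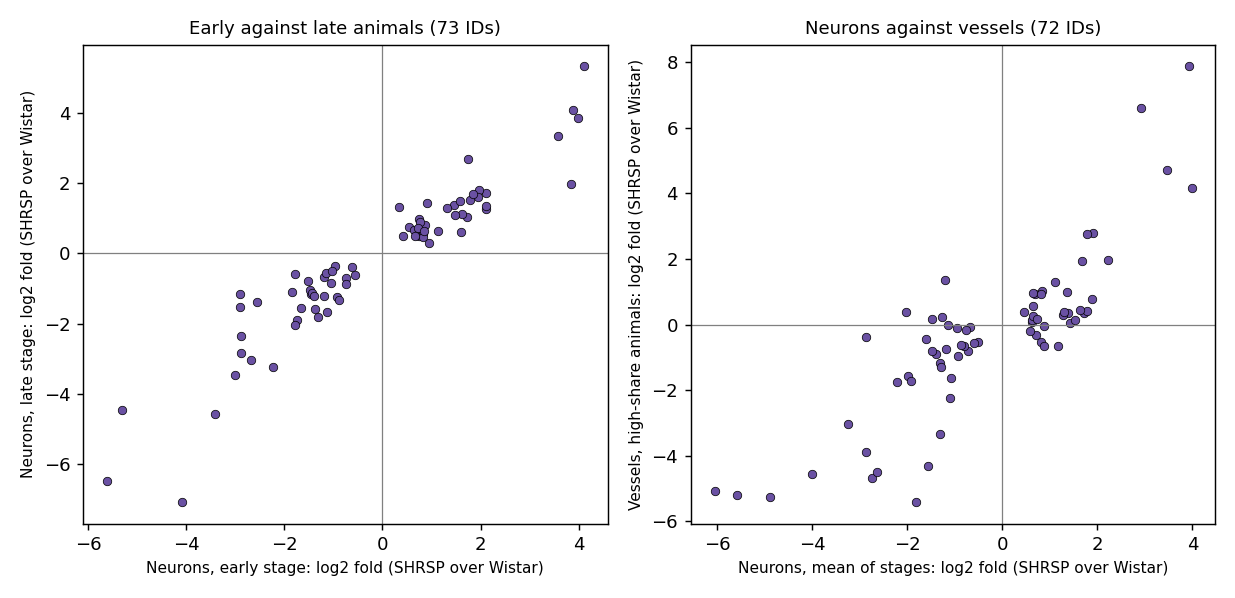
Log2 fold of SHRSP over Wistar for the IDs called in neurons over the mean of stages. Left, early (x axis) against late animals (y axis), where all 73 IDs share their sign; right, neurons (x axis) against the vessels of the 11 high-share animals (y axis), where 62 of 72 do.

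In vessels, 9 IDs differed between the strains over the mean of stages, 8 higher and 1 lower in SHRSP. ENSRNOG00000038999 was 8.72-fold higher in SHRSP (log2 fold 3.13, SE 0.39, adjusted p = 1.97e-11), and all 10 SHRSP vessel libraries lay above all 9 Wistar libraries. It measured 1201 ± 884 CPM in early and 391 ± 101 in late SHRSP vessels (n = 5 each), against 84.5 ± 113 (n = 5) and 72.9 ± 20.2 (n = 4) in Wistar. It was the 1 ID called in both materials, where independent lists give 0.0195 (Fisher's exact test, p = 0.0194). That p rests on this ID alone, and the lists are not independent, since both come from the same animals. ENSRNOG00000017628 was 5.14-fold higher in SHRSP vessels (log2 fold 2.36, SE 0.38, adjusted p = 2.05e-06), while in neurons it stood at 2.41 to 7.58 CPM with a log2 fold of -0.33 (SE 0.48). That vessel call was lost in limma voom (adjusted p = 0.104), without animal 377 (0.0581), in the high-share animals (0.569) and with the library set in limma voom (0.157), and over its alternatives the adjusted p ran from 2.28e-09 to 0.569. ENSRNOG00000031033 was lower at log2 fold -0.52 (SE 0.12, adjusted p = 0.0362), and it did not pass in 18 of 28 alternatives (adjusted p 0.00081 to 1), 10 of them without a single animal (346, 350, 351, 353, 354, 368, 378, 379, 383 or 386). The balance of the calls turned in DESeq2 (44 higher and 95 lower) and without animal 383 (5 and 7), while DESeq2-type scaling gave 12 higher and 0 lower. The count was 25, 21, 18 and 15 without animals 349, 368, 377 and 386.

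In vessels, 56 of the 68 neuron strain calls tested there had the same sign as in neurons. Besides ENSRNOG00000038999, the IDs named for neurons did not pass in vessels: ENSRNOG00000005826 had a log2 fold of 5.41 (SE 1.41, adjusted p = 0.0783), ENSRNOG00000017895 of -7.07 (SE 1.79, adjusted p = 0.068) and ENSRNOG00000001199 of -5.89 (SE 1.74, adjusted p = 0.153). Several of these libraries had no counts, among them 7 of 10 SHRSP libraries for ENSRNOG00000017895, and the fitted folds are then no bounds.

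In early vessels 28 IDs differed between the strains, 24 higher and 4 lower in SHRSP. ENSRNOG00000038999 (log2 fold 3.83, SE 0.54) and ENSRNOG00000058039 (log2 fold 2.26, SE 0.38, adjusted p = 1.49e-05) were higher, and ENSRNOG00000031033 (log2 fold -0.89, SE 0.17) and ENSRNOG00000036802 (log2 fold -2.36, SE 0.49, adjusted p = 0.00194) were lower. Of the 24 higher IDs, 13 were vessel-enriched and 0 neuron-enriched, and of the 4 lower IDs 0 and 2. The median log2 fold was 1.32 over vessel-enriched and -1.35 over neuron-enriched IDs, but 1.01 and 0.07 when both kinds were chosen in Wistar animals alone. Vessel-enriched IDs, which were chosen in a fit that included these libraries, took 9.65% ± 0.857 of the counts in early SHRSP and 4.0% ± 2.12 in early Wistar vessel libraries (SD, n = 5 each; exact permutation test, p = 0.00794, adjusted p = 0.0159 over 2 tests), and 5.71% ± 1.61 and 4.47% ± 0.852 in the late groups (exact permutation test, p = 0.206). Among the 4 low-share early animals of each strain the shares were 9.80% ± 0.911 and 4.2% ± 2.39 (exact permutation test, p = 0.0286, the smallest these groups allow). The mean log2 CPM of vessel-enriched over neuron-enriched IDs was 4.26 and 2.56 in the early groups (exact permutation test, adjusted p = 0.109 over 32 tests), and with IDs chosen in Wistar animals alone it was 5.55 and 4.94 (exact permutation test, p = 0.246). Counts of 0 were involved in 8 of the 28 calls, 7 without a count in early Wistar and 1 without a count in early SHRSP vessels. The count rested on single animals and on the tool: it was 1137 without SHRSP animal 383 (133 higher and 1004 lower, with 24 of the 28 among them), 54 without Wistar animal 349, 7, 12 and 18 without Wistar animals 340, 343 and 346, 4 in limma voom and 486 in DESeq2 (152 higher and 334 lower, with 20 of the 28). With the library set as a term 28 passed, 13 higher and 15 lower, of which 14 were among the first 28. ENSRNOG00000058039 was lost without animal 377 (adjusted p = 0.211), with only the early groups (0.0557) and with the set as a term (0.0709), ENSRNOG00000036802 in limma voom (0.503), and ENSRNOG00000031033 without animal 346 (0.124), with DESeq2-type scaling (0.0669), in DESeq2 (0.335) and in limma voom (0.547). Over the alternatives the adjusted p ran from 7.12e-10 to 0.211 for the first, from 2.28e-06 to 1 for the second and from 1.91e-06 to 1 for the third.

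In late vessels 0 IDs passed in edgeR, with 102 at an unadjusted p under 0.05, where chance gives 550.6. DESeq2 gave 11 calls and limma voom 18. In edgeR 274 of 10504 IDs had such a p with only the late groups, and 999 of 13816 in the high-share animals. The early and late groups shared their estimate of the spread, so 28 early and 0 late calls do not show a change with stage. ENSRNOG00000038999 had the smallest p in late vessels (log2 fold 2.42, SE 0.56, adjusted p = 0.153) and was the 1 call with only the late groups in the fit (log2 fold 2.42). The change of the strain difference with stage passed for 1 ID in vessels, ENSRNOG00000061934. It averaged 68.0 ± 136 CPM in early SHRSP vessels with 2 of 5 libraries at 0, and 9.26 ± 12.2 CPM in late Wistar vessels with 1 of 4 at 0, while the 5 early Wistar and the 5 late SHRSP libraries had no counts. Against 3 counts over such a group the mean was at least 368-fold higher in early SHRSP and at least 60.7-fold higher in late Wistar vessels. Both bounds rest on 1 library, animal 377 at 310.1 CPM and animal 350 at 26.9 CPM, without which they are at least 40.5-fold and 22.1-fold. They cover counting error only and not the spread between animals. The strain difference of this ID in late vessels did not pass in edgeR (log2 fold -7.98, SE 2.39), but did in DESeq2 (Wald test, adjusted p = 9.54e-07). The call was lost in limma voom (adjusted p = 0.747), with the set as a term (0.0571) and in the high-share animals (1), over alternatives from 1.17e-18 to 1. Without animal 374 or 377 the ID fell under the filter on low counts and was not tested. Between the materials, the strain difference differed for 0 of 12117 IDs in edgeR, with 686 at an unadjusted p under 0.05; DESeq2 gave 320 calls, limma voom 1, and edgeR without the animal block 3. Leaving out animals gave 5 calls there without 368 or 383, 2 without 374 or 377 and 1 without 346. For the change with stage in vessels it gave 8 without 383, 3 without 386, 3 other IDs without 377, 2 without 349, 353, 354, 368, 378 or 380, and 0 without 374.

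The neurons of late and early animals differed in 959 IDs in SHRSP (663 higher and 296 lower in late animals) and in 1009 in Wistar (633 higher and 376 lower). ENSRNOG00000028362 was 4.09-fold higher in late SHRSP neurons (log2 fold 2.03, SE 0.31, adjusted p = 0.00407), and ENSRNOG00000003453 was 3.35-fold lower (log2 fold -1.74, SE 0.29). In Wistar, ENSRNOG00000009894 was 8.43-fold higher in late neurons (log2 fold 3.08, SE 0.38, adjusted p = 0.000134), from 7.17 ± 2.83 to 60.9 ± 28.0 CPM. ENSRNOG00000024923 was lower in the late animals of both strains, 2.41-fold in SHRSP (log2 fold -1.27, SE 0.22) and 2.96-fold in Wistar (log2 fold -1.57, SE 0.24). The strains shared 356 higher and 109 lower calls, where independent lists give 38.7 and 10.3, and 1485 of the 1503 IDs called in either had the same sign in both. Neuron-enriched IDs were 410 of the 663 higher calls in SHRSP and 398 of the 633 in Wistar, and 3302 of the 10833 IDs tested. Vessel-enriched IDs took 1.37% ± 0.237 of the counts in neuron libraries of early and 0.845% ± 0.0875 of late SHRSP animals (SD, n = 5 each). In Wistar they took 1.2% ± 0.161 (n = 5) and 0.74% ± 0.138 (n = 4). The share of neuron-enriched IDs fell too, from 15.7% to 15.3% in SHRSP and from 16.0% to 13.7% in Wistar. These shares are over all counts, and that of the most abundant ID rose from 9.13% to 23.1% in SHRSP and from 11.2% to 32.5% in Wistar. After TMM scaling, the median log2 fold of vessel-enriched IDs was -0.43 in SHRSP and -0.31 in Wistar, against 0.31 and 0.33 for neuron-enriched IDs. The mean log2 CPM of vessel-enriched over neuron-enriched IDs went from -0.70 to -1.37 in SHRSP (exact permutation test, p = 0.00794, the smallest possible, adjusted p = 0.109 over 32 tests) and from -0.78 to -1.39 in Wistar (exact permutation test, p = 0.0317, adjusted p = 0.113). DESeq2-type scaling gave 796 higher and 184 lower calls in SHRSP, and 717 and 285 in Wistar. Limma voom gave 3104 in SHRSP, 1679 higher and 1425 lower, and 992 higher and 461 lower in Wistar.

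The stage calls in neurons went with the library sets. With the set as a term 0 IDs passed in either strain in edgeR, with 484 and 517 at an unadjusted p under 0.05, and limma voom gave 2 and 4. In that fit the folds of the called IDs kept a median of 55.6% of their size in SHRSP and 57.0% in Wistar, with the same sign in 949 of 959 and 1008 of 1009, and their median SE rose from 0.29 to 0.37 and from 0.32 to 0.39 on the log2 scale. Each strain has 1 early animal in the high-share set, so that term rests on 1 animal per strain. In the high-share animals alone 4 and 0 IDs passed. Without the early animals 349 and 383, 1577 and 1894 passed. Leaving out single animals gave in SHRSP 180 calls (without 379), 214 (380), 366 (386), 423 (377), 426 (374), 432 (384), 613 (378) and 1441 (383). In Wistar it gave 197 (353), 338 (350), 475 (354 or 368), 635 (340) and 1847 (349). With only the 2 groups compared the counts were 2033 and 83.

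**Figure D4:**
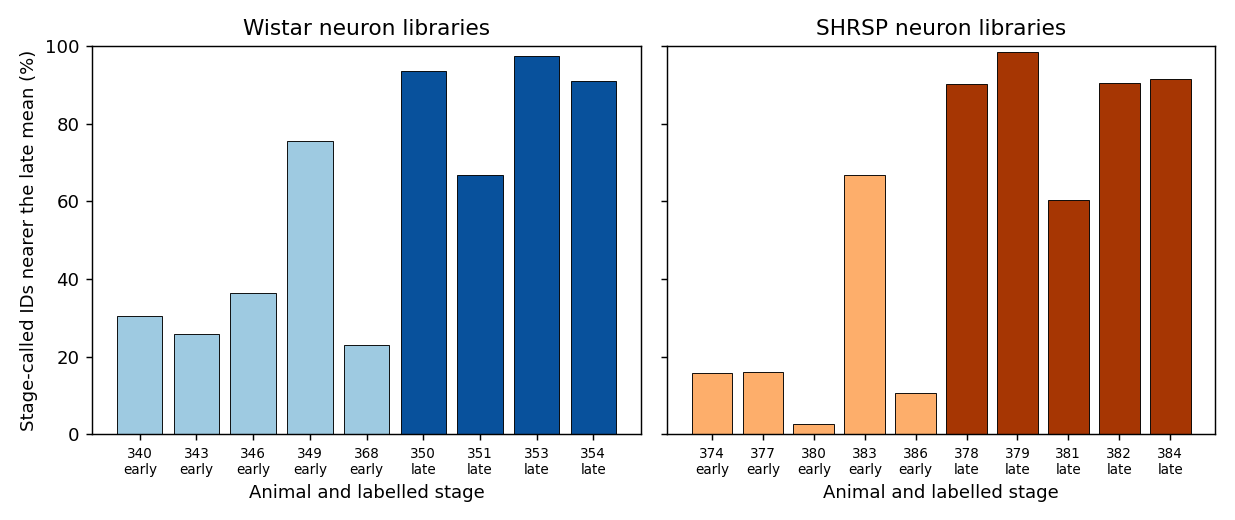
Percent of the IDs called for stage in neurons in which each animal lay nearer the late than the early mean of its strain, with the IDs called in fits that left out the animal itself and animals 349 and 383. Early animals 349 (75.4%) and 383 (66.7%) lie above the other 8 early animals (2.62% to 36.3%) and within the range of the 9 late animals (60.3% to 98.5%).

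In vessels the stage comparison passed for 1 ID in each strain. ENSRNOG00000015550, the ID with the smallest p between the materials, was 2.63-fold lower in late SHRSP vessels (log2 fold -1.40, SE 0.25, adjusted p = 0.00026), from 5370 ± 2569 to 2038 ± 591 CPM on the scale of the vessel libraries (SD, n = 5 each). ENSRNOG00000031033 was 1.90-fold lower in late Wistar vessels (log2 fold -0.92, SE 0.18, adjusted p = 0.00531). The first was lost in 9 of 20 alternatives (adjusted p 2.03e-07 to 1), among them DESeq2 (0.118), no filter (0.117) and without animals 374 (0.0606), 377 (0.288), 383 (0.0522) or 384 (0.145). The second was lost in 12 of 19 (adjusted p 0.000399 to 1), among them DESeq2-type scaling (0.108), no filter (0.352), only the 2 groups (0.493) and without animals 346 (log2 fold -0.59, adjusted p = 1), 350 (0.152), 353 (0.0577) or 368 (0.0741). DESeq2 gave 358 calls in SHRSP, 324 higher and 34 lower, and 34 in Wistar, 31 higher and 3 lower. Leaving out SHRSP animal 383 gave 1310 calls in SHRSP (1275 higher and 35 lower), 377 gave 3, and 374 or 384 gave 0. In Wistar the count was 6 without animal 349, 4 without 343, 3 without 354, 2 without 340 or 351 and 0 without 353. With the library set as a term 0 IDs passed in either strain.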

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

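The tests of the stage calls in neurons, of more vessel material in early SHRSP vessel captures and of a partial loss of countable reads, and the signs in vessels of the other stage's animals, were chosen after the results were seen, and so was the rule that a share must pass a bound with its whole 95% interval. The tests in high-share animals were worded after the library sets had been seen in the data.

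Of 90 groups of values tested for a single animal far from the others, 7 held one, where chance gives 4.5. Neuron libraries of early Wistar animal 343 had 9501 IDs with a count, against 12849 to 14045 in the others of its group, and those of early SHRSP animal 374, whose 1198386 counts were the fewest of all, had 11987, against 13705 to 13975. At equal depth these were 9151 against 12227 to 12871, and 11987 against 12700 to 12969. The most abundant ID took 40.6% of the counts in the vessels of early Wistar animal 349, against 9.73% to 16.3%, and 24.3% in the neurons of late Wistar animal 351, against 35.0% to 35.5%. In early SHRSP animal 383 it took 17.7% in vessels, against 6.45% to 7.54%, and 21.8% in neurons, against 5.37% to 6.74%. The log2 CPM of ENSRNOG00000001199 was 0.69 in the neurons of late SHRSP animal 379, against 1.75 to 2.02. In vessels the strain difference of ENSRNOG00000061934 changed with stage at a fitted log2 fold of -18.82, which is no bound because 2 groups had no counts.

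The stage calls in neurons may come from the library set that all late and 2 early animals share. Over IDs called without these animals, early animal 349 lay nearer the late mean in 75.4% and early animal 383 in 66.7%, above the other early animals (2.62% to 36.3%) and within the range of the late ones (60.3% to 98.5%). The stage of the animals is not excluded, because 66.7% is under the 80% set as its bound and most folds kept their sign with the set as a term. A wrong stage label of these 2 animals also stays open: 0 late animals were in the low-share set, which argues against a swap within a strain but not against a single wrong label. Stage and library set cannot be told apart here, since 1 early animal per strain separates them.

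The strain calls in early vessels may reflect more vessel material in the early SHRSP captures. Of the higher calls, 41.7% were among IDs vessel-enriched in Wistar animals alone, against 1.02% of all IDs tested (Fisher's exact test, p = 1.37e-14). That test takes IDs as independent, though they come from the same captures, and the 1.02% was not matched for abundance. It therefore cannot decide whether the captures held more vessel material. With animals as units, the score of the IDs chosen in Wistar animals did not differ beyond chance (exact permutation test, p = 0.246). The median log2 fold of neuron-enriched IDs was -1.35 over those chosen in all animals, but 0.07 over those chosen in Wistar animals. Unstable counts in libraries with few IDs stay open, since 10 of the 28 calls (35.7%, exact 95% interval 18.6% to 55.9%) reached an unadjusted p under 0.05 with the same sign in high-share animals. These animals are all late except 349 and 383, which helped to make the calls. A strain difference of the early stage alone could therefore also be missed there. A strain difference present in both stages and materials also stays open. It had 5 of 28 calls in early neurons (17.9%, interval 6.06% to 36.9%), a share under the 20% set beforehand as the bound against it, but with an interval that includes 20%, and 21 of the 28 could be tested there. The real contrast gave 28 calls, and 29 of 100 splits of the animals gave as many, up to 1582 (SHRSP animals 374, 377, 380 and 386 with Wistar animal 346), so chance is not excluded and the samples hold another structure.

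The 73 strain calls in neurons are a candidate for a difference between the strains themselves. In the vessels of the high-share animals, whose neurons helped to choose the IDs, 62 of 72 had the same sign. In vessels of other animals, those of the other stage, 18 of 23 early neuron calls did, 5 of them at an unadjusted p under 0.05. All 4 late neuron calls did too, 3 of them at such a p, but they are also early calls and so no separate evidence. Unequal vessel material is argued against as the cause of most calls, though not of the 4 that were vessel-enriched (5.48%, exact 95% interval 1.51% to 13.4%, with 239 of the 10833 IDs tested vessel-enriched). The test for a complete loss of counted reads through a sequence difference found 0 calls without counts in a strain. It asked for exactly 0 counts over all neuron libraries of a strain, which a few stray reads prevent, so a near-complete loss stays open. ENSRNOG00000017895 had 16 and 21 counts in early and late SHRSP neurons, against 684 and 355 in Wistar. A partial loss of reads in one strain stays open, as no genome was used. Its test gave 11 calls that differed between the materials at an unadjusted p under 0.05, where chance gives 3.65 (one-sided binomial test, p = 0.000981), which met the bound written against it. That bound was wrong, because IDs chosen for a large difference in neurons differ more often from vessels by that choice alone.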

How the results depend on the processing

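The library set as a term, either set alone and the fits without animals 349 and 383 were chosen after the data were seen, and the other alternatives before. No named ID reversed its sign where it passed the threshold in the main fit or in the alternative. Reversals where it passed in neither were not counted. The balance of higher and lower calls turned for vessels. In DESeq2 it did so for early strain (152 higher, 334 lower), the mean (44, 95), the change with stage (93, 37) and stage in SHRSP (324, 34) and Wistar (31, 3), and without animal 383 for early strain (133, 1004), the mean (5, 7), the change (5, 3) and SHRSP (1275, 35). It also turned with the set as a term for early strain (13, 15), in high-share animals for the change (17, 1) and SHRSP (23, 0), in limma voom in these for the mean (5, 7), and without 349 and 383 for the change (4, 2) and SHRSP (1968, 40). In neurons the early strain balance turned without a filter (10, 13), without animal 343 (16, 19) and in low-share animals (0, 1), the late one in limma voom (20, 15; 52 and 24 with the set), and stage in SHRSP in the high-share animals (0, 4) and with the set in limma voom (0, 2; Wistar 0, 4), while the mean of 36 and 37 is too even to have one. Of 1017 alternative values of named IDs, 918 kept their side of the threshold, 17 gained it and 82 lost it. DESeq2-type scaling gave 55 early strain calls in vessels, 2 for the change with stage, 2 for stage in SHRSP and 3 in Wistar. Without a filter these were 16, 3, 0 and 4, and late strain calls in neurons 7. The filter of at least 10 counts gave 2 for stage in Wistar vessels and 1 for the strain difference between materials. DESeq2 gave in vessels 486 (early), 11 (late), 139 (mean of stages), 130 (change with stage), 358 (SHRSP stage) and 34 (Wistar stage), in neurons 73, 16, 159, 1480 (SHRSP) and 1550 (Wistar), and between materials 6351 and, for strain, 320. Limma voom gave in vessels 4, 18, 5, 0 and 6 (SHRSP), in neurons 60, 35, 180 and 3104 (SHRSP), and 1 for strain between materials. With only the 2 groups compared, vessels gave 9 (early), 1 (late), 6 (SHRSP) and 0 (Wistar), and neurons 5, 17, 2033 and 83. With the set as a term, vessels gave 5 (mean), 0 (change), 0 and 0 (stage), and neurons 0 and 0 (stage); in limma voom vessels gave 4 (early), 3 (mean), 0, 0 and 0, and neurons 60, 76, 251, 2 and 4. The causes of these changes were not tested.

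Low-share animals alone gave 11 early strain calls in vessels and 1 in neurons. High-share animals alone gave in vessels 1 (late), 2 (mean), 18 (change), 23 (SHRSP) and 0 (Wistar), in neurons 19 (late), 30 (mean; 207 in limma voom), 4 (SHRSP) and 0 (Wistar), and 18 for strain between materials. Without animals 349 and 383, vessels gave 6 (change), 2008 (SHRSP) and 2 (Wistar), and neurons 1577 and 1894. Without the animal block the materials differed in 2013 IDs and the strain difference between them in 3; the pairing of libraries is read from the animal numbers. Leaving out each animal in turn gave in vessels 7 (340) to 1137 (383) early, 0 to 0 late, 6 to 25 (349) for the mean, 0 (374) to 8 (383) for the change, 0 (374, 384) to 1310 (383) in SHRSP and 0 (353) to 6 (349) in Wistar. In neurons it gave 8 (377, 380, 386) to 35 (343) early, 2 (354) to 5 (351) late, 40 (353) to 122 (343), 0 to 0, 180 (379) to 1441 (383) and 197 (353) to 1847 (349). Between materials it gave 3566 (368) to 4218 (354), and 0 to 5 (368, 383) for strain. Not run were the exclusion of shallow libraries, as 0 lay under the bound, and the marker covariate and gene lists, which need names. Vessel libraries had a higher median depth than neuron libraries but varied more between animals (coefficient of variation 1.59 against 0.354): simulated 8-fold changes were found in 2% to 28% of cases there and 81% to 98% in neurons.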

Other observations

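The splits of the animals were planned before the data were examined, and none of the tests here was chosen after the results were seen. Each contrast was refitted with the animals split at random into groups of the same sizes, the real split included. The bound set beforehand for chance was not adjusted over the contrasts, so passing it narrowly does not exclude chance. The smallest share possible was 1 of 100 splits, or 1 of 40 across materials, and it is not adjusted either. In neurons the real split alone reached its count for the mean of stages (73 calls, 1 of 100 splits as large, highest other 8) and the early strain difference (24 calls, 1 of 100, highest other 22), which argues against chance. For the late strain difference (4 calls, 4 of 100, highest other 120) chance is not excluded, and the highest split points to a structure of the samples. For the stage difference in SHRSP chance is argued against (959 calls, 1 of 100, highest other 827). That other split set the 4 low-share animals and 381 against the rest, so it kept 4 of the 5 early animals together and holds the library set too. For the stage difference in Wistar (1009 calls, 2 of 100) chance is not excluded without that adjustment. The split of the 4 low-share animals against the rest gave 1883 calls, so a structure of the samples gives more calls than stage. The change of the strain difference with stage in neurons gave 0 calls in edgeR, with 254 at an unadjusted p under 0.05 and 0 in DESeq2 and limma voom, and all 100 splits were as large. In vessels the mean of stages passed the bound (9 calls, 2 of 100, highest other 13), but chance is not excluded without adjustment over the contrasts. Nor is it excluded there for the change with stage (1 call, 37 of 100, highest other 6), stage in SHRSP (1 call, 24 of 100, highest other 5) and stage in Wistar (1 call, 11 of 100, highest other 8, from the split by library set). The late strain difference in vessels gave 0 calls in edgeR, and all 100 splits were as large. It had 102 IDs at an unadjusted p under 0.05, where chance gives 550.6, and 11 calls in DESeq2 and 18 in limma voom. Between materials, limma voom gave 4218 calls, more than any other split (1 of 40 splits, highest other 2353), which argues against chance. It gave 1 call for the strain difference between materials (19 of 40, highest other 671), where chance is not excluded.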
